A study of Arabidopsis lyrata and Arabidopsis thaliana with 9 samples.

How the data were processed

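RNA was measured in 9 directional RNA-seq libraries of wild-type plants after bolting: 3 of A. lyrata leaves, 3 of A. lyrata inflorescences and 3 of A. thaliana inflorescences. RNA was extracted as total RNA with a plant spin-column kit and an added DNA digestion, per the labels' protocols. Each library had 1 table of gene identifiers with raw counts, as the authors deposited them, with whole numbers that sum to a different total in each library. The submitters' processing notes name TAIR10 for all samples. The aligner, the counting tool, whether counting used the strand of the reads, and the genome used for A. lyrata reads are not given in the sources used here. Groups and replicate numbers were taken from the labels.

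The A. thaliana tables hold 27176 gene models, of which 26690 matched a locus of the TAIR10.1 annotation used here for gene names, positions and lengths. Only nuclear loci are listed in them. The A. lyrata tables hold 32644 numeric identifiers. The A. lyrata reference table used here, of another identifier system, holds 34365 genes, and 0 of the identifiers matched, so A. lyrata genes were not named. The planned gene-level test between species, the planned gene-list tests in both comparisons, the planned overlap of the 2 comparisons and a joint fit of all 9 libraries all need shared or named genes and were not made.

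A. lyrata inflorescences and leaves were compared with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 19638 genes and removed 13006, counts were scaled with TMM, and a quasi-likelihood F test with tissue as the only term was followed by Benjamini-Hochberg adjustment with a threshold of 0.05. The biological coefficient of variation was 0.165. CPM in the restricted classes and of named identifiers uses raw library totals. A fold against a group at 0 counts is a lower bound against 3 counts over the group, and intervals and floors cover counting error only. Replicate numbers were checked for pairing, and no sign of it was found, though so few libraries cannot exclude shared plants or harvests. The test was tried on simulated counts for 18656 genes, drawn from the real inflorescence means for both groups, the real depths and 1 common dispersion. Of these genes, 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. It recovered 22.4% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold, and 7 of 143 calls were unchanged genes. A far larger share of genes passed in the real comparison, so these rates do not describe it.

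At the library level, counts were thinned at random to 6263918 per library, 5 draws each, before genes with a count were tallied, and group differences were tested with exact two-sided permutation tests over 16 tests. Within each group, every pair of replicate libraries differed by more than sampling noise, with chi-square values per gene of 2.46 to 27.1, so no library repeated another. Each was counted as a replicate by its label. The check cannot tell separate plants from separate libraries of 1 RNA sample. In A. thaliana, CPM was computed from the raw counts. There were 19 gene lists with 270 members fixed before the data were examined, of which 267 were measured. HPR1 and F3PH were left out because the annotation gives their loci another symbol and does not hold the list symbol among the synonyms, and AOP2 because it was not listed in the counts used here. Members whose locus has no symbol in the annotation were kept by locus. Of the members measured, 58 overlap a gene on the opposite strand and are less certain. Differences between A. thaliana libraries were set against 10000 random lists of the same size matched on mean expression, as log2 ratios of CPM plus 0.5. This step was tried on a list with a planted shift, which reached percentile 100, and on 300 unchanged lists, of which 4.33% fell outside the central 95%. The unchanged lists were also drawn at random from the same genes. A share near 5% follows from that draw and does not cover lists whose members vary together.

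Before the data were examined, named genes were set to be all floral MADS-box genes, the genes with the highest and lowest fitted fold changes among those past the threshold with at least 20 CPM in the higher group and no overlap between groups, and up to 4 members of each other list. Without names, at most 2 identifiers that rose and 2 that fell are printed. Since no list could be tested, the members named for A. thaliana are the 2 with the highest and the 2 with the lowest mean CPM of each list, a choice made after the data were seen, and members tied at 0 were given as a count. Alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters, a test against 2-fold (glmTreat), a replicate block, removal of genes above 1% of counts and leaving out each library. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.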

Results

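The series measured RNA in flowering shoots and leaves of a pair of related plants: Arabidopsis lyrata, a perennial, and Arabidopsis thaliana, the annual model plant. Strand-specific (directional) RNA-seq libraries were made from total RNA of wild-type plants after bolting, the stage at which the flowering stem has grown out. There were 9 libraries in 3 groups of 3 biological replicates. They came from leaves of A. lyrata and from inflorescences of either species. A. lyrata was grown in long days at 18 °C and A. thaliana in a greenhouse in long days, so species and growth conditions differed together. The deposited files gave raw counts per gene. A. lyrata leaf libraries held 11419322 to 13786151 counts, A. lyrata inflorescence libraries 7211749 to 12729487, and A. thaliana inflorescence libraries 6263918 to 14004158. The study concerned the evolution of the binding sites and target genes of a master regulator of flower development, and from knowledge of the study that regulator was SEP3 (SEPALLATA3), a MADS-box transcription factor. Levels are CPM, counts scaled to a common library total, given as mean ± SD over the 3 libraries of a group (n = 3) unless values per library are named.

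The first comparison asked which genes of A. lyrata differ between inflorescences and leaves. The A. lyrata files identify genes only by number, and none of the 32644 numbers matched the A. lyrata reference table used here, so A. lyrata genes are described by count, level and a few identifiers, not by function. Inflorescences had more strongly tissue-biased genes than leaves. Of 19638 genes tested, 2003 were higher in inflorescences by 8-fold or more and 836 were lower by 8-fold or more. At 32-fold or more there were 1215 higher and 320 lower. A total of 517 genes were inflorescence-restricted, with 5 CPM or more in all 3 inflorescence libraries and 0.5 CPM or less in all 3 leaf libraries, against 95 leaf-restricted genes by the mirrored rule. There were 179 genes with no count in any leaf library and 5 CPM or more in every inflorescence library, and 13 genes with the reverse.

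In all, 14010 of the tested genes (71.3%) differed between the tissues at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 7319 were higher in inflorescences and 6691 were lower. Changes of 2-fold or more made up 4440 of the higher and 3513 of the lower genes, and the median log2 fold change of all tested genes was 0.05, coded inflorescence minus leaf. The TMM scaling centres fold changes near 0, so this median and the balance of higher and lower genes are relative to it. When the test asked for evidence of a change beyond 2-fold (glmTreat), 6234 genes passed, 3580 higher and 2654 lower.

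**Figure D1:**
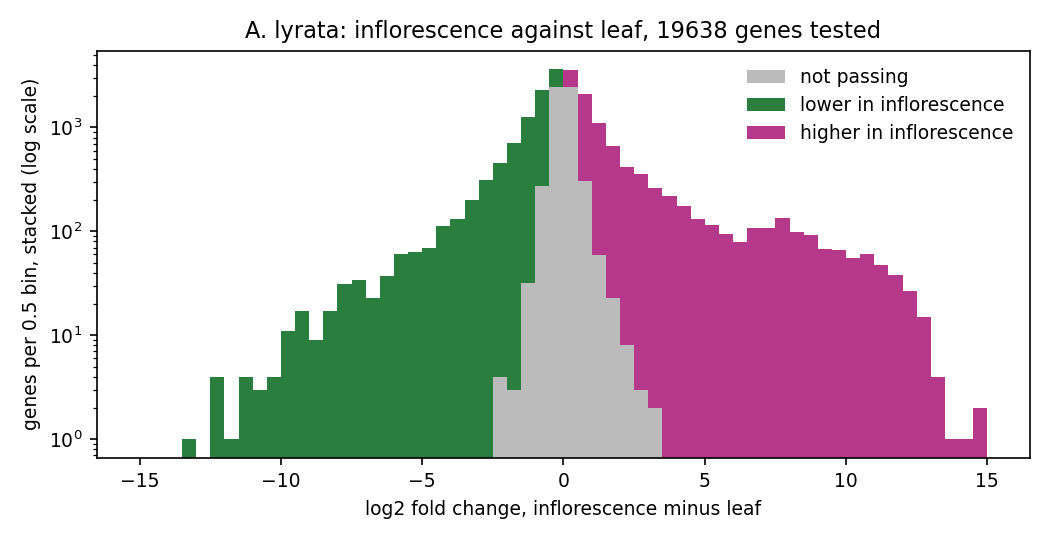
Number of A. lyrata genes (stacked, log axis) by log2 fold change between inflorescences and leaves (horizontal axis, bins of 0.5, positive when higher in inflorescences), for 19638 genes tested with 3 libraries per tissue. Grey genes did not pass an adjusted p of 0.05 and coloured genes did; the right tail holds 1215 passing genes at 32-fold or more and the left tail 320. Fold changes of genes with few or no counts in one tissue depend on the prior count of the fit.

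The 2 most abundant leaf genes were far lower in inflorescences. The most abundant leaf gene stood at 18838 ± 1192 CPM in leaves and 886 ± 24.0 CPM in inflorescences, and the next at 13178 ± 492 and 693 ± 28.5 CPM. Genes lower in inflorescences by 2-fold or more held 43.4% ± 0.845 of leaf counts and 10.8% ± 0.148 of inflorescence counts. Genes higher in inflorescences by 2-fold or more held 31.8% ± 0.297 of inflorescence counts and 4.55% ± 0.154 of leaf counts. Both sets were chosen by fold change in these same libraries, which fixes the direction of the 2 contrasts. The shares describe how much of each library the sets held. The 517 inflorescence-restricted genes held 3.65% ± 0.108 of inflorescence counts.

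The naming rule ordered genes by fitted fold change, which depends on the prior count for genes at 0 in one tissue, so the 4 identifiers it gave are examples and not the largest changes by the bounds printed. Those that rose were 923119 and 314430. Gene 923119 reached 323 ± 236 CPM in inflorescences and had no counts in leaves, which makes it at least 3944-fold higher against a floor of 3 counts over the leaf group (edgeR adjusted p = 0.000367). Inflorescence library 1 alone held 566 CPM of it, and without that library the bound was 2459-fold. Gene 314430 reached 310 ± 48.0 CPM with no leaf counts, at least 3784-fold higher (edgeR adjusted p = 8.17e-07). Those that fell were 906183 and 941819. Gene 941819 stood at 379 ± 83.8 CPM in leaves and had 2 counts in inflorescences, a ratio of 6151 with a 95% counting interval of 1702 to 50796 (edgeR adjusted p = 1.47e-07). Gene 906183 ranged from 1.67 to 231 CPM over the leaf libraries and had no inflorescence counts, at least 975-fold lower in inflorescences (edgeR adjusted p = 0.0173). Leaf library 2 decided that bound, which was 225-fold without it, and limma-voom gave the gene an adjusted p of 0.307.

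At the level of whole libraries, more genes had counts in A. lyrata inflorescences than in leaves. With every library thinned to 6263918 counts, 22727 ± 24.0 genes had at least 1 count in inflorescences and 20400 ± 337 in leaves, a difference of 2327 genes that was 1505 at 10 counts or more. The 10 most abundant genes of each library took 5.33% ± 0.874 of inflorescence counts and 8.32% ± 0.215 of leaf counts, and the 100 most abundant took 16.6% ± 0.604 and 22.8% ± 0.282. Each of these differences separated all 3 libraries of one tissue from all 3 of the other. The exact two-sided permutation test gave p = 0.1 for each, the smallest p that 3 libraries against 3 allow, and an adjusted p of 0.107 over the 16 library-level tests made.

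**Figure D2:**
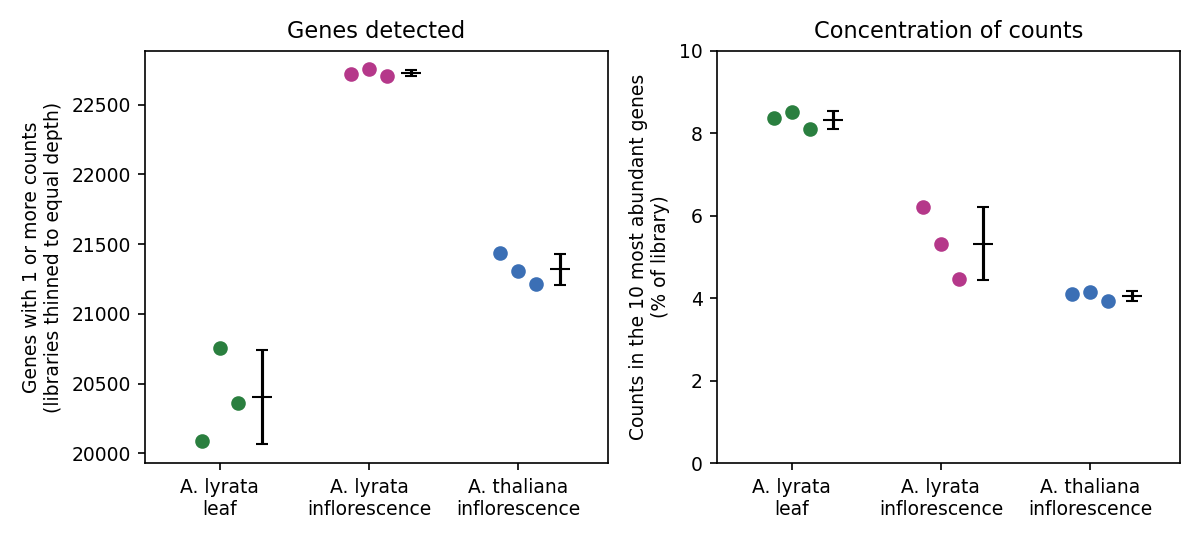
Genes with at least 1 count after thinning to 6263918 counts (left axis, truncated) and percent of counts in the 10 most abundant genes (right axis, from 0) for each of the 9 libraries. Points are libraries, and the bars beside them are the mean and SD of 3 libraries; A. lyrata inflorescences lie at 22727 ± 24.0 detected genes and A. lyrata leaves at 20400 ± 337.

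The second comparison asked how gene expression in inflorescences differs between A. lyrata and A. thaliana. The A. thaliana files list 27176 gene models by locus and share no identifiers with the A. lyrata files, so no gene was tested between species. At equal depth, A. lyrata inflorescences had 22727 ± 24.0 genes with a count and A. thaliana inflorescences 21320 ± 112, a difference of 1407 genes that was 384 when at least 10 counts were asked for. As a share of the genes listed, the order was the other way, 69.6% ± 0.0734 in A. lyrata and 78.5% ± 0.411 in A. thaliana. The 10 most abundant genes took 5.33% ± 0.874 of counts in A. lyrata and 4.06% ± 0.116 in A. thaliana, a difference of 1.27 percentage points that was 0.832 without A. lyrata inflorescence library 1. The exact two-sided permutation test gave p = 0.1 for each of these, the smallest possible, with an adjusted p of 0.107 over 16 tests. The tables of the 2 species list different numbers of genes, and growth conditions differed with species. The levels of named genes that follow are those of A. thaliana inflorescences alone. CPM is not divided by gene length, so highest and lowest here refer to counts, and the order of genes can differ once length is considered.

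In A. thaliana inflorescences, SEP3 had the highest level of the 16 floral MADS-box genes listed, at 267 ± 9.76 CPM, which ranked 526 among the 27176 models. SEP3 (AT1G24260) lies on chromosome 1 of TAIR10.1 at 8593536 to 8596123 on the minus strand, and the counted model has 8 exons. AP1, which specifies sepals and floral meristem identity, followed at 225 ± 9.20 CPM. The petal and stamen identity genes PI and AP3 stood at 210 ± 4.79 and 152 ± 4.01 CPM, and AG, the stamen and carpel identity gene, at 97.1 ± 3.62 CPM. Of the other SEPALLATA genes, SEP2 stood at 135 ± 8.14, SEP1 at 94.1 ± 4.73 and SEP4 at 19.97 ± 1.49 CPM. FUL was at 33.3 ± 2.36, AGL6 at 25.2 ± 3.77 and CAL, a close relative of AP1, at 10.4 ± 1.38 CPM. The fruit and ovule genes SHP2, SHP1 and STK were at 17.1 ± 0.353, 16.7 ± 5.62 and 16.4 ± 3.61 CPM. TT16 and AGL13 were the lowest, at 0.308 ± 0.162 and 0.249 ± 0.223 CPM, so 14 of the 16 stood at 10 CPM or more. SEP1, SHP1, SHP2 and STK overlap genes on the opposite strand, and SHP1 and SHP2 are similar in sequence, so their levels are less certain.

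**Figure D3:**
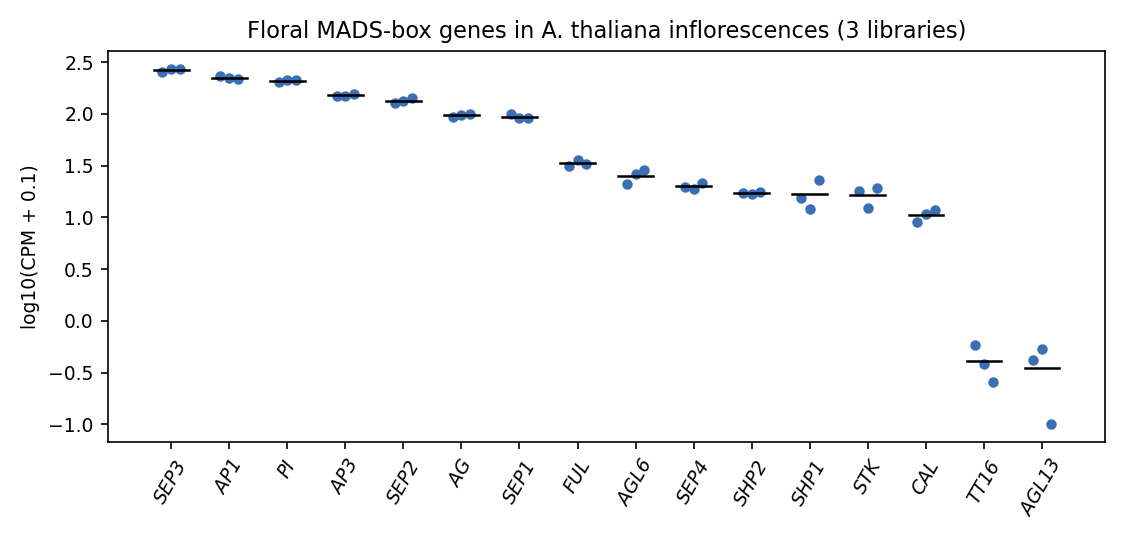
Levels of the 16 floral MADS-box genes in A. thaliana inflorescences, as log10 of CPM plus 0.1 (vertical axis). Points are the 3 libraries and lines their means; SEP3 stands highest at 267 ± 9.76 CPM, and AGL13, with no count in library 3, lowest at 0.249 ± 0.223 CPM.

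Among other regulators of flowering, all 6 flowering-time MADS-box genes were detected. FLM was the highest at 45.7 ± 1.87 CPM and SOC1 next at 25.9 ± 2.16 CPM, while AGL24 was at 6.11 ± 1.09 and FLC, the vernalization-responsive repressor of flowering, at 3.601 ± 0.907 CPM. Of 26 floral and meristem regulators, 10 stood at 10 CPM or more. The highest were ANT, a growth regulator of floral organs, at 82.7 ± 3.77 CPM and ETT, an auxin response factor of the carpel, at 74.99 ± 7.71 CPM. The lowest were KNU at 0.182 ± 0.124 CPM and CLV3, which encodes the peptide that restricts stem cells, with no counts among 26598287, which allows up to 0.113 CPM. That limit covers counting error only. The counted entry of CLV3 is 1 gene model (AT2G27250.3), and how reads were assigned to models is not known, so its RNA may be missed. WUS, the stem cell regulator that acts with CLV3, was at 16.2 ± 2.11 CPM and was named after its value was seen.

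Levels of anther genes spanned a wide range. Of 20 anther and tapetum genes, the tapetum being the layer that feeds developing pollen, 15 stood at 10 CPM or more, with a list median of 54.8 ± 4.98 CPM. The pollen coat genes GRP17 and EXL4 were the highest at 1780 ± 131 and 546 ± 10.4 CPM, and MYB80 and DYT1 the lowest, MYB80 at 2.31 ± 0.498 CPM and DYT1 at 0.798, 0.143 and 0.158 CPM in libraries 1, 2 and 3. Of 12 genes expressed in pollen, VGD1 and PPME1, pectin methylesterases of the pollen tube, were the highest at 329 ± 110 and 163 ± 60.7 CPM, and HAP2 and DUO1 the lowest at 0.868 ± 0.0754 and 0.651 ± 0.342 CPM. VGD1 and VGDH1 are similar neighbours and could share reads. Meiosis genes had a list median of 3.35 ± 0.281 CPM over 9 genes. The median of their mean levels, 3.40 CPM, lay at percentile 26.1 of 10000 random lists of the same size, not matched on expression. DMC1, the meiotic recombinase, was the highest at 17.6 ± 1.71 CPM, ahead of MSH5 at 5.35 ± 1.73 CPM, and ASY1 and SPO11-1 were the lowest at 1.35 ± 0.644 and 0.840 ± 0.487 CPM. All 18 cell cycle genes stood at 10 CPM or more, with a median of 54.3 ± 3.00 CPM. TSO2 and HINKEL were the highest at 101 ± 11.9 and 81.0 ± 9.01 CPM, and AUR2 and CDKB1;1 the lowest at 20.3 ± 0.641 and 12.6 ± 0.866 CPM.

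Photosynthesis genes were abundant in the A. thaliana inflorescences. All 43 listed stood above 100 CPM and together they took 7.16% ± 0.0956 of counts, with a list median of 1277 ± 27.8 CPM. RBCS1A, a small subunit of Rubisco, was the most abundant gene of the libraries at 8539 ± 60.4 CPM, followed by LHCB1.3 at 5787 ± 168 CPM, while RBCS1B and PETE1 were the lowest of the list at 494 ± 43.5 and 127 ± 4.91 CPM. The RBCS and LHCB1 genes are near-identical families and could share reads. Photorespiration genes had a median of 670 ± 30.3 CPM over 7 genes, from GLDP1 at 1396 ± 78.0 and SHM1 at 901 ± 52.4 CPM to CAT2 at 554 ± 33.8 and GOX1 at 539 ± 35.0 CPM. Senescence genes had a median of 9.65 ± 4.64 CPM over 10 genes. NYC1 and PAO, enzymes of chlorophyll breakdown, were the highest at 105 ± 6.64 and 50.3 ± 1.96 CPM, WRKY53 was at 1.70 ± 0.396 CPM, and SAG12 had no counts, which allows up to 0.113 CPM.

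The highest members of the defence list were VSP1 and LOX2. VSP1, a vegetative storage protein, was at 2541 ± 335 CPM and LOX2, a lipoxygenase of jasmonate synthesis, at 1323 ± 137 CPM, while the defensin PDF1.2a was at 0.0238 ± 0.0412 CPM. PAD3, an enzyme of camalexin synthesis, had nearly all its counts in library 1, at 1.60 CPM against 0.0714 in library 2 and none in library 3. PR2 (7.18, 0.286 and 0.316 CPM) and PR1 (2.71 CPM in library 1 alone) did likewise, and were named after their values were seen. Of 9 defence genes at 1 CPM or more, 4 were higher in library 1 than in library 2 and 7 than in library 3. Both list medians, -0.10 and 0.08 in log2 ratio, lay inside the random lists. The list median was 5.25 ± 1.76 CPM over 12 genes. Of 23 glucosinolate genes, the myrosinases TGG2 and TGG1 were the highest at 4507 ± 316 and 2564 ± 115 CPM, AOP3 was at 0.177 ± 0.0320 CPM, and MYB76 had no counts, with the same limit of 0.113 CPM. The glucosinolate list median was 14.2 ± 3.92 CPM. In the flavonoid pathway, CHS, the entry enzyme, stood at 957 ± 55.0 CPM and FLS1, which makes flavonols, at 429 ± 61.0 CPM, while DFR, the first enzyme of the anthocyanin branch, was at 0.207 ± 0.246 CPM and BAN at 0.106 ± 0.184 CPM. The list median over 14 genes was 25.6 ± 1.88 CPM. CHS overlaps a gene on the opposite strand.

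Of 13 cold and dehydration genes, KIN2 and KIN1, a similar neighbouring pair, were the highest at 263 ± 9.38 and 223 ± 24.97 CPM, and GOLS3 and CBF1 the lowest at 0.148 ± 0.143 and 0.0527 ± 0.0912 CPM, with a list median of 43.4 ± 7.09 CPM. Of 12 clock and photoperiod genes, LHY stood at 232 ± 17.3 and PRR7 at 129 ± 4.14 CPM, while FT, the flowering signal made in leaves, was at 0.858 ± 0.345 and ELF4 at 0.436 ± 0.171 CPM, with a median of 15.2 ± 0.952 CPM. Terpene genes of open flowers had a median of 15.3 ± 5.94 CPM over 6 genes, with TPS11 and TPS14, both terpene synthases, at 63.9 ± 12.9 and 25.6 ± 11.04 CPM and TPS21 at 4.01 ± 2.12 CPM. TPS24 stood at 7.66 CPM in library 1 and at 0.643 and 0.158 CPM in libraries 2 and 3. Of 6 trichome genes, TTG1 and TRY were the highest at 48.4 ± 1.34 and 18.2 ± 1.17 CPM, and CPC and GL1 the lowest at 0.492 ± 0.447 and 0.231 ± 0.240 CPM, with a median of 2.71 ± 0.708 CPM. Markers of seeds and roots were at or near 0. Of 8 seed storage genes, 6 had no counts and CRA1 was the highest at 0.390 ± 0.222 CPM, and of 6 root genes, 5 had no counts and WER was at 0.0770 ± 0.0800 CPM. FLC, DUO1, ASY1, AUR2, CDKB1;1, LHCB1.3, GLDP1, CAT2, GOX1, WRKY53 and TPS14 also overlap genes on the opposite strand, so their levels are less certain. Means under 1 CPM rest on few counts, and leaving out 1 library moved those of AGL13, KNU, PDF1.2a, DFR, BAN, GOLS3, CBF1, GL1, CPC and WER by over 1.5 times.

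The A. thaliana libraries differed among themselves in many of these lists. All 10 pollen genes with a mean of at least 1 CPM were higher in library 1 than in library 3, with a median log2 ratio of 0.58, above the highest of 10000 random lists matched on mean expression (0.44). They were also higher in library 2 than in library 3, with a median log2 ratio of 1.06 (highest random list 0.48). Between libraries 1 and 2, 3 of 10 were higher in library 1, and the median of -0.44 lay below the lowest random list (-0.36). VGD1 stood at 323, 441 and 222 CPM in libraries 1, 2 and 3. Among the floral terpene genes, 5 of 6 were higher in library 1 than in library 3, with a median log2 ratio of 1.35 against a highest matched random list of 0.77, and all 6 were higher in library 2 than in library 3, with a median of 1.01 against 0.78. In the anther and tapetum list the median log2 ratio of library 1 over library 3 was -0.14, with 5 of 19 genes higher in library 1. It lay near the low end of its random lists (-0.18 to 0.26, percentile 0.125), so this list leaned higher in library 3. Of 18 cell cycle genes, 0 were higher in library 2 than in library 3, with a median of -0.19 against a lowest random list of -0.22. Of 19 glucosinolate genes, 1 was higher in library 1 than in library 2, and the median log2 ratio of -0.37 lay below the lowest matched random list (-0.22). Of 10 cold and dehydration genes, 1 was higher in library 1 than in library 2, with a median of -0.25 against a lowest random list of -0.24. Other lists also lay near the ends of their random lists. For library 1 over 2, cell cycle (16 of 18 higher) lay at percentile 99.64 and meiosis (8 of 8) at 99.44. Photorespiration (1 of 7) lay at 0.135 and photosynthesis (9 of 43) at 0.325. For library 1 over 3, flavonoid (2 of 10) lay at 0.2 and clock and photoperiod (8 of 10) at 99.43. Libraries 1 and 3 had close to the same depth, 6263918 and 6330211 counts. Random lists hold genes drawn independently, so a list whose members vary together leaves their range more easily. These ratios compare single libraries of one group and carry no test of a condition.

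**Figure D4:**
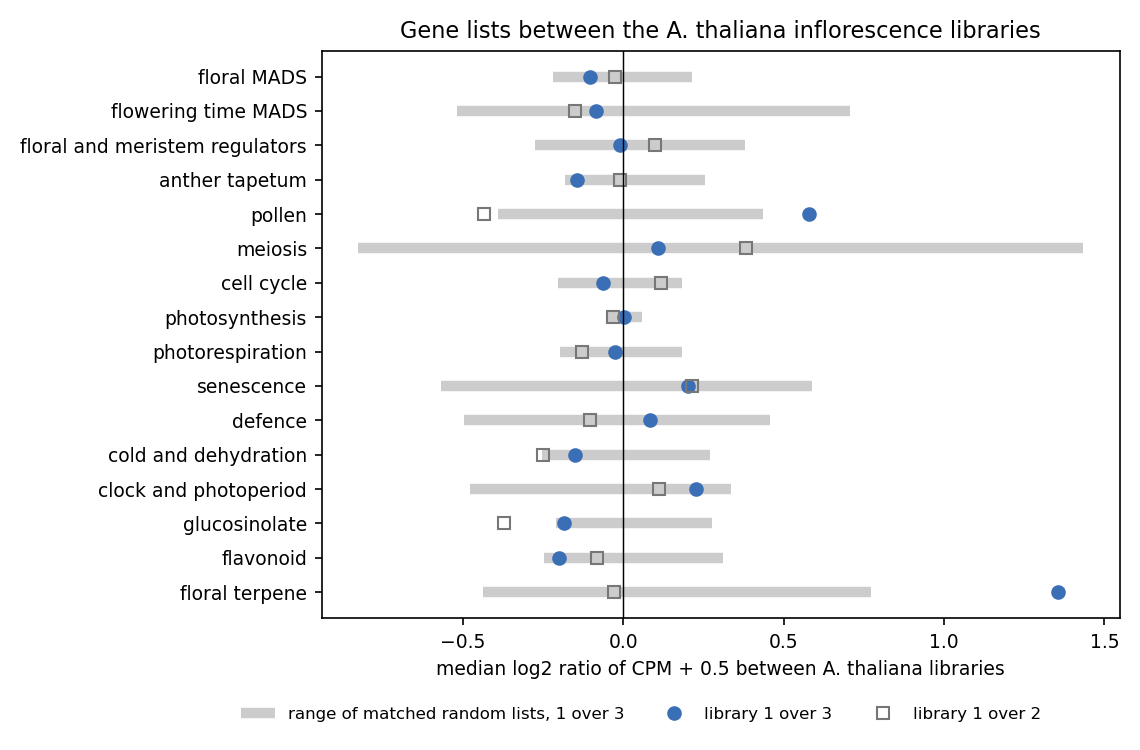
Median log2 ratio of CPM plus 0.5 between A. thaliana inflorescence libraries for each gene list with at least 4 members at a mean of 1 CPM or more (filled points, library 1 over 3; open squares, library 1 over 2). Grey bars span 10000 random lists matched on mean expression for library 1 over 3; the pollen list at 0.58 and the floral terpene list at 1.35 lie above their bars.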

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

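Alternatives for the number of genes that differed between A. lyrata tissues and for the 4 named identifiers were planned, and those for the restricted genes, the library-level differences and the A. thaliana lists were chosen after the data were seen. Between inflorescences and leaves, 14010 genes passed, and other scalings, DESeq2, limma-voom, other filters and removal of abundant genes gave 11848 (stricter filter, 15985 genes tested) to 15224 (no filter, 25668 tested). The test against 2-fold gave 6234, with 3580 higher and 2654 lower, by its construction. Leaving out each library gave 13069 to 14076 genes, of which 12741 to 13222 were shared with the full comparison. In none of these settings did a gene that passed in both turn its direction, and the share of higher genes lay between 50.9% and 57.4%. The median log2 fold change was 0.05, and 0.16 with no filter. The scalings tried all centre fold changes near 0, so they are no independent check of that median or of the share of higher genes. With a replicate block, 13735 genes passed. Deviations of same-numbered leaf and inflorescence libraries correlated at 0.089, 0.140 and -0.125, and among the leaf libraries number 1 alone correlated best with its own number. These values gave no sign of pairing, but so few libraries cannot exclude shared plants or harvests. There were 440 to 600 inflorescence-restricted A. lyrata genes and 97 to 138 leaf-restricted A. lyrata genes over their alternatives. Of the 4 named identifiers, 906183 lost its call under limma-voom (adjusted p 0.307, range 5.03e-06 to 0.307 over its alternatives) and was not tested under the stricter filter. Of the library-level differences in detected genes, inflorescence minus leaf was 1505 at 10 counts in place of 2327 at 1 count, and A. lyrata minus A. thaliana was 1770 without thinning and 384 at 10 counts in place of 1407. In percent of counts, inflorescence minus leaf was -6.16 for the 100 most abundant genes and -0.62 for the most abundant gene in place of -2.995 for 10, since each counts other genes, and A. lyrata minus A. thaliana was 0.832 without A. lyrata inflorescence library 1 and 0.410 for the most abundant gene in place of 1.27. The causes of the other shifts were not tested. In A. thaliana, no list's median gene percentile moved by 10 or more when counts were divided by model length. Single genes moved more. The clock gene GI went from percentile 81.3 to 61.8, HINKEL from 89.8 to 79.2 and the anther gene A9 from 74.0 to 92.9. Orders of single genes by CPM are therefore not robust to length, though SEP3 stayed the highest of the floral MADS-box genes. The alternatives planned for the species test, list tests and overlap were not run, nor was a joint fit or removal of organelle genes, because identifiers were not shared, A. lyrata genes were not named and no organelle loci were listed. By counting error alone, depth limits A. thaliana gene models at 0 to under 0.113 CPM.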

Other observations

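All tests of explanations in this part were chosen after the results were seen.

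Over all genes, list members included, 87 of 13159 A. thaliana genes with a mean of at least 10 CPM differed by 2-fold or more between inflorescence libraries, and 81 of them were lowest in library 3. The genes named here were chosen after their values were seen. GPAT5, an acyltransferase of suberin synthesis, stood at 17.6, 18.6 and 0.316 CPM in libraries 1, 2 and 3, the last from 2 counts. ABCG20, a half-size transporter, stood at 18.2, 18.9 and 2.21 CPM, GLP8, a germin-like protein, at 21.7, 20.9 and 2.84 CPM, and FLA3, a fasciclin-like arabinogalactan protein, at 14.8, 14.4 and 2.69 CPM.

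Pollen genes were lowest in A. thaliana library 3. Depth is argued against, because the median log2 ratio of library 1 over library 3, of nearly equal depth, was 0.579 and the highest of 10000 matched random lists reached 0.435. Dilution of all floral RNA by other tissue is argued against as well, since the anther and tapetum list had a median of -0.145 and its highest member reached 0.398. A hypothesis is that library 3 may hold fewer older flowers: the floral terpene list, fixed for open flowers, had a median of 1.354 against a highest random list of 0.771. Between libraries 1 and 2 the pollen and terpene lists did not move together. The pollen median of -0.435 lay below its lowest random list (-0.359), and the terpene median of -0.029 lay inside its random lists (-0.414 to 0.414). The labels give no floral stage, so no biological group was tested, and a difference in growth or harvest between replicates stays open: 8 of 9 senescence genes were higher in library 1 than in library 3 (median 0.20, inside the random lists), and ASN1 and DIN10, which respond to darkness and sugar and were picked after their values were seen, stood at 265, 213 and 111 CPM and at 265, 175 and 103 CPM in libraries 1, 2 and 3.

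In A. lyrata, 454 genes with an inflorescence bias of 32-fold or more and at least 20 CPM varied more between inflorescence libraries than matched genes, and between libraries 1 and 3 their log2 ratios had an interquartile range of 1.51 against 0.196 in stable genes matched on expression, the widest of the 3 pairs. It was 0.900 against 0.170 between libraries 1 and 2 and 0.587 against 0.149 between libraries 2 and 3, and 97, 145 and 24 of the 454 differed by 2-fold or more in pairs 1 and 2, 1 and 3, and 2 and 3 (of the 145, 104 were higher in library 3 and 41 in library 1). The 10 most abundant leaf genes took 1.276% to 1.344% of counts in the inflorescence libraries. In equal parts of leaf and inflorescence RNA, the leaf part alone would bring 4.143%. These values argue against leaf tissue lowering all 454 genes 2-fold in a library. Leaf tissue would lower all of them by about 1 common factor, so the values bear on a common shift and do not test the spread. Among 166 leaf-biased genes, the interquartile range between leaf libraries was 1.09 against 0.244 in matched genes for libraries 1 and 3, 1.003 against 0.261 for 1 and 2, and 0.626 against 0.265 for 2 and 3. No biological explanation was tested, and floral or leaf stage stays open.

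For the number of genes that differed between A. lyrata tissues, 1 of the 10 splits of the 6 libraries gave as many genes, the real one with 14010, and the highest of the other 9 gave 0 in edgeR. Those splits had 15 to 101 genes at an unadjusted p under 0.05 in edgeR, 0 adjusted calls in limma-voom and 0 to 33 in DESeq2. With 10 splits no share under 0.05 can be reached. Each of the other 9 splits also put leaf and inflorescence libraries on both sides. The tissue difference then counted as spread within groups, which by itself keeps the calls near 0. Those counts therefore do not calibrate the 14010.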
